A study of Mus musculus with 20 samples.

How the data were processed

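Total RNA of 4 mucAB lines and 1 control culture of BALB 3T3 cells was measured on Affymetrix Mouse Expression Arrays 430A and 430B, 2 arrays per culture and design. Per the labels' protocols, the cells grew in medium with 10% serum, with neomycin for some of the cell types, a plasmid with mucAB behind the mouse metallothionein promoter was introduced and neomycin-resistant clones were picked, RNA was extracted with a column kit, and biotin-labelled cRNA was made from 100 ng of total RNA. The deposited values are signal intensity on a linear scale from the MAS5 algorithm, made with Affymetrix Expression Console 1.1 per the submitters' processing notes. The 2% trimmed mean of every deposited array was 1000, as checked here, so each array had been scaled to the same level; the genome build behind the design is not given in the sources used here. Scaling to a common level leaves differences between arrays meaningful only relative to the bulk of probe sets. The number of arrays limits the precision.

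Values were taken to log2 with no offset. Of 22690 and 22575 probe sets on 430A and 430B, 64 controls on each were left out. A probe set was tested where the highest of its 5 culture means lay above the median of all log2 signals of its design (signals of 240.3 and 404.2), which left 12275 and 14412. Symbols came from the platform annotation, updated through Entrez identifiers in a GRCm38.p6 gene table used for names only. On 430A, 20393 probe sets had 1 symbol, 691 several and 1606 none, and on 430B 14674, 245 and 7656. No gene was named from a probe set with several. Of these, 20364 and 14499 matched the gene table.

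All tests used limma 3.58.1 in R 4.3.3, with a variance prior that follows mean signal, Benjamini-Hochberg adjustment and a threshold of 0.05. The mean of the 4 lines was compared with the control on 5 culture averages, so that the spread between lines sets the error and the single control is assumed to vary like a line. Each line was also compared with the control, and with the mean of the other 3 lines, over 10 arrays in 5 groups, and a moderated F test compared the 4 lines. Probe sets called the same way in all 4 line contrasts were counted, beside the counts of independent lists and of 100 simulated draws with unchanged lines. Of 33 gene lists written before the data were examined, the 26 with at least 5 tested genes on 430A were tested with camera on the culture averages, with 1 probe set per gene (the brightest), a preset correlation of 0.01 and, beside it, an estimated one. The lists were also tested for each line against the control and against the other 3 lines, over the 10 arrays, where the estimated correlation comes from the residuals between the 2 arrays of a culture.

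On simulated data in which all 5 cultures, the control included, differed by the spread measured between lines on 430A, shuffled over probe sets, the test on culture averages recovered 0 of 100 probe sets changed 2-fold and 37 of 100 changed 4-fold, and the count over 4 lines recovered 68 and 89 but also made 458 false calls among 12275 probe sets, where the test on culture averages made 2. With cultures alike it recovered 83 and 96, and the count over 4 lines 65 and 82 with 0 false calls beside 12. On 430B with cultures differing, the recoveries were 0 and 0, and 14 and 36 with 197 false calls among 14412. With cultures alike on 430B, they were 20 and 44, and 10 and 34 with 0 false calls. The test on culture averages made 0 false calls on 430B with cultures differing and 4 with cultures alike.

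Genes were named by a rule written before the data were examined, from probe sets with exactly 1 symbol and 1 per gene. It took the 10 largest rises and falls on 430A and 5 on 430B, at least 2-fold in the mean and in the same direction in all 4 lines, among called probe sets. Because fewer than 10 were called on either design, the ranking was made, as the rule provides, among those called the same way in all 4 line contrasts. It further took up to 3 genes per direction and line that differed at least 4-fold, on the signals as deposited, both from the control and from the other 3 lines, up to 4 called members per list or else the 2 with the smallest p given as values, and proto-oncogenes called at least 2-fold in at least 3 lines. Other list members called in all 4 lines, and the interferon examples, were named after their values were seen. A group under the median signal of its design counts as low: the fold is then given as at least that, with each low array at the higher of that median and its own value, and no fold is given where both sides are low.

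The alternatives were quantile normalization, no low-signal filter, a stricter filter (mean above the 60th percentile), log2 of signal plus 32, a variance prior without trend, leaving out each array, arrays as units, leaving out each line, the replicate number as a block, each other culture in the place of the control, the mean over the probe sets of a gene, and an estimated correlation. Leaving out each line for the counts over the lines and for the lists was added after seeing the data.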

Results

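Expression was measured in BALB 3T3 cells, an established mouse embryonic fibroblast line that is used to score transformation in culture, with and without the bacterial plasmid genes mucAB, which encode an error-prone DNA polymerase and its partner protein. The series asked whether carrying the foreign gene goes along with altered expression of known oncogenes. There were 4 mucAB lines, labelled 12, 52, 63 and 72, and 1 untreated control culture, C2. Each culture was hybridised to 2 arrays of each of 2 designs, 430A and 430B, which gives 20 arrays in 10 groups of 2. The labels do not say whether the 2 arrays of a culture came from separate cultures, so p-values over arrays measure only the spread between these samples, which may be technical. The labels call the lines transformed by mucAB and the control non-treated, and do not say whether the word means a transformed phenotype or the introduction of the gene. The lines had also been selected for neomycin resistance and cloned, so mucAB, transformation, selection and cloning cannot be told apart here. No probe set of either annotation table carries a mucA or mucB symbol, so expression of the introduced gene was not measured.

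The 2 arrays of a culture correlated at 0.975 to 0.983 on 430A and at 0.803 to 0.838 on 430B, against 0.933 to 0.957 and 0.757 to 0.808 between cultures. The closest other array was of the same culture for 10 of 10 arrays on each design. The median SD between the 2 arrays of a culture was 0.173 on the log2 scale on 430A and 0.571 on 430B, so 430B gave the less precise values. Gapdh 3' to 5' signal ratios were 0.888 to 1.09 on 430A and 1.01 to 1.27 on 430B, and those of Actb 1.41 to 1.89 and 1.61 to 2.03. The signal of the B1 repeat control on 430A was 19900 and 18300 in line 12, 16700 and 16200 in line 52, and 14300 and 15300 in line 72. It was 7320 and 8030 in line 63 and 6830 and 7720 in the control.

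With the lines as the units of replication, 3 genes on 430B were higher in the mucAB lines than in the control and no probe set on 430A passed the test. Tcim, a small regulator linked to Wnt signalling, was 4.69-fold higher (log2 difference 2.23 ± 0.33 SE, 4 lines, adjusted p = 0.0341). Dusp4, a MAP kinase phosphatase, was at least 4.22-fold higher (adjusted p = 0.0460), and Ddias, a DNA damage-induced apoptosis suppressor, at least 2.58-fold higher (adjusted p = 0.0308) over the mean of the lines. The direction was the same in 4 of 4 lines, but with arrays as units Tcim was called in 4 lines, Dusp4 in 3 (not line 52, adjusted p = 0.11) and Ddias in 0 (adjusted p = 0.0731 to 0.195). The 2 control arrays differed widely for these genes, with signals of 695 ± 561 for Tcim, 248 ± 305 for Dusp4 and 679 ± 899 for Ddias (mean ± SD, n = 2). On 430A limma called 0 of 12275 probe sets, the lowest adjusted p was 0.186, and 619 had an unadjusted p under 0.05 where chance gives 613.8. On 430B, 580 of 14412 had an unadjusted p under 0.05 where chance gives 720.6. The same test on simulated 430B data made 0 false calls with cultures that differed and 4 with cultures alike. Each was 1 draw that also held 100 probe sets changed 2-fold and 100 changed 4-fold. Those false calls are therefore no matched benchmark for the 3 calls. The 3 calls were lost when the variance prior had no trend, without the low-signal filter, with a stricter filter, or when any 1 array of a mucAB line was left out (0 calls each). Leaving out control replicate 1 gave 1 call and leaving out replicate 2 gave 10. Without control replicate 1 the log2 difference was 1.29 for Tcim, 1.98 for Dusp4 and 0.52 for Ddias. Without replicate 2 it was 3.17, 5.83 and 5.46.

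When the arrays were the units, 368 probe sets on 430A were called the same way against the control in all 4 lines, 194 higher and 174 lower. Among the named genes with higher signal, Itgbl1, an integrin beta-like secreted protein, stood at 1390 ± 144 in line 12, 1390 ± 260 in line 52, 520 ± 130 in line 63 and 1990 ± 192 in line 72, against 92.4 ± 17.2 in the control (mean ± SD, n = 2). This was at least 4.91-fold higher over the lines. Anxa8, a calcium-dependent phospholipid-binding protein, was at least 3.72-fold higher, Fosl1, a subunit of the AP-1 transcription factor, at least 1.84-fold, and Msln, the cell surface protein mesothelin, at least 1.32-fold. For Msln and Fosl1 the control arrays lay at 27.6 ± 33.8 and 121 ± 137. The Fosl1 call in all 4 lines was lost when any 1 array was left out (adjusted p = 0.0516 to 0.14) except line 63 replicate 1 or control replicate 2, and the Anxa8 call without line 12 replicate 1 or 2 or control replicate 2 (adjusted p = 0.0863, 0.0563 and 0.0772). Diaph3, Tnfrsf21, Cdc6, Glcci1, Dyrk3 and Pim1 were also called higher in all 4 lines, but the mean of the lines and the control both lay under the chip's median signal of 240.3, and no fold is given. Pim1, a serine/threonine kinase, read 191 ± 17.2, 207 ± 102, 446 ± 36.7 and 170 ± 3.11 in lines 12, 52, 63 and 72 and 53.1 ± 2.82 in the control.

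The genes lower in all 4 lines on 430A were led by Gnat2, a transducin alpha subunit, which was at least 5.68-fold lower, with 1430 ± 76.5 in the control and 198 ± 41.5 to 264 ± 8.93 in the lines. Postn, which encodes the matrix protein periostin, fell 4.78-fold, from 20400 ± 1570 in the control to between 2540 ± 58.3 in line 63 and 8090 ± 1160 in line 12. Ptx3, a secreted pentraxin, fell 4.04-fold, Peg3, an imprinted zinc finger gene, 4.03-fold, and Tcf7l1, a transcription factor of the Wnt pathway, 3.68-fold. The Tcf7l1 values differed little between lines (889 ± 24.8 to 1080 ± 62.1, against 3780 ± 1140 in the control). Of the protocadherins, which are cell adhesion molecules, Pcdhb7 and Pcdh18 were at least 1.71-fold and at least 2.48-fold lower. Pcdhb7 was no longer called in all 4 lines without either array of line 63, of line 72 or of the control. Pcdhb9 read 807 ± 47, 386 ± 17.4 and 1070 ± 39.8 in lines 12, 63 and 72 and 87 ± 32.5, under the chip's median, in line 52, against 1850 ± 186 in the control. Wnt5a, a secreted Wnt ligand, was at least 3.74-fold lower, and Lgals7, a galectin, at least 2.79-fold lower.

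**Figure D1:**
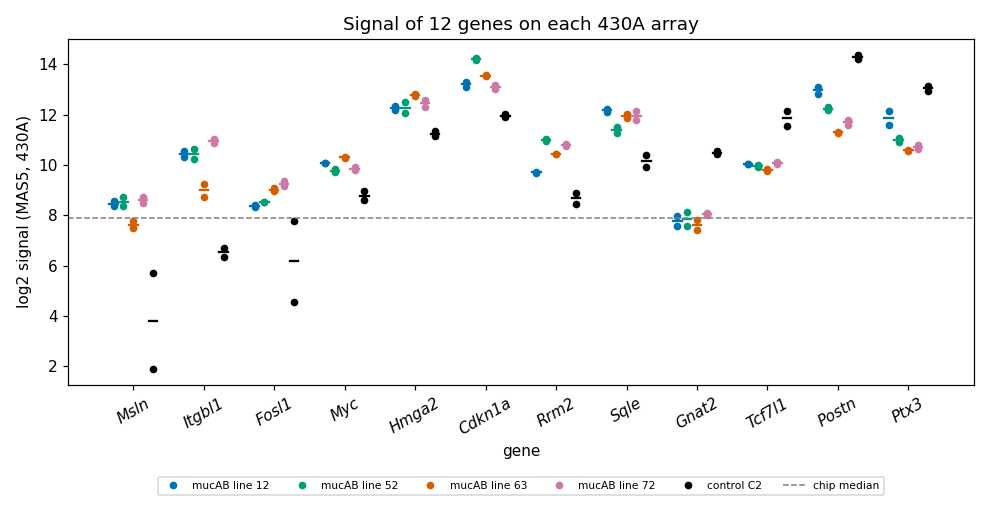
Log2 MAS5 signal on 430A (y axis) of 12 named genes (x axis) on each array; points are arrays, short bars are means of 2 arrays, colours are cultures, and the dashed line is the chip's median. The control lies below all 4 lines for Msln to Sqle and above them for Gnat2 to Ptx3, and its 2 arrays are far apart for Msln and Fosl1.

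The adjusted p of these named 430A genes in the weakest of their 4 contrasts lay between 1.12e-05 for Itgbl1 and 0.0365 for Pcdhb9. Simulated unchanged lines gave 0 such probe sets in each of 100 draws. That outcome was nearly fixed in advance, so it is no benchmark for the 368. Independent lists of the observed sizes would share 1 higher and 1.53 lower. In 1 simulated data set all 5 cultures, the control included, differed by the spread measured between lines. There, 458 probe sets without a simulated change were called the same way in all 4 lines, more than the 368 observed. The spread was shuffled over probe sets, so the spread of a noisy probe set could fall on a precise one and add calls. The 458 is therefore no matched benchmark for the 368. Part of the excess of the 368 over independent lists may come from the shared control arrays, which cannot be split. The control was not the culture with the most such calls. When each line took the control's place, 349 probe sets were called the same way against all 4 other cultures for line 12, 566 for line 52, 340 for line 63 and 181 for line 72. Leaving out control replicate 1 lowered the 368 to 190, and leaving out line 72 replicate 1 or 2 lowered it to 198 or 217. Without the variance trend the calls of Anxa8 (adjusted p = 0.0723) and Pcdhb9 (adjusted p = 0.0633) were lost, and without the low-signal filter those of Pcdhb9 (adjusted p = 0.0656), Pcdh18 (adjusted p = 0.0706) and Dyrk3 (adjusted p = 0.0726). Quantile normalization also removed that of Pcdhb9 (adjusted p = 0.0611), and the offset of 32 that of Dyrk3 (adjusted p = 0.0626).

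**Figure D2:**
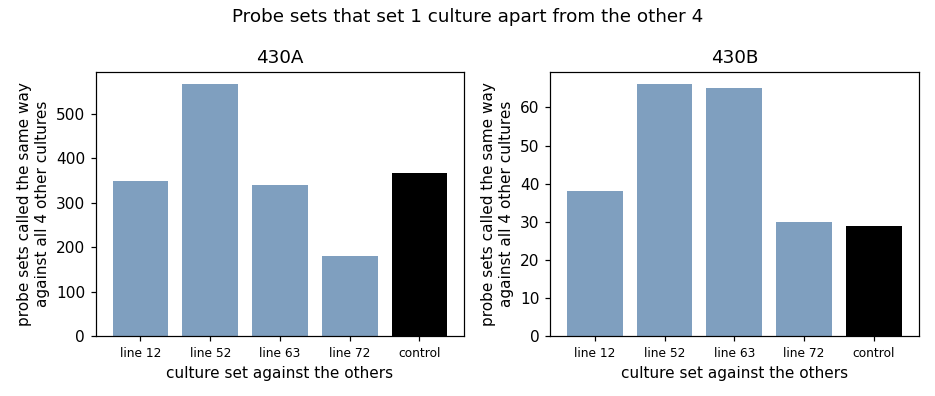
Number of probe sets (y axis) called the same way against all 4 other cultures when each culture (x axis) is set against the others, on 430A and 430B; the control is black. On 430A the control has 368 and the lines 181 to 566, and on 430B the control has 29 and the lines 30 to 66.

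On 430B, 29 probe sets were called the same way in all 4 lines, 17 higher and 12 lower. Besides Tcim, the higher genes with the largest differences were Dynap, a membrane protein that was 4.39-fold higher, Tm4sf1, a tetraspanin-like surface protein (at least 2.17-fold), Emc8, a subunit of an endoplasmic reticulum membrane complex (at least 2.14-fold), and Kif20b, a mitotic kinesin (at least 1.34-fold). Ptn, the growth factor pleiotrophin, fell 3.48-fold, from 6010 ± 8.74 in the control to between 1570 ± 651 and 2060 ± 630 in the lines. Cemip, a hyaluronan-binding protein, fell 3.30-fold, although its other tested probe set had the opposite sign. Bend5, Sned1 and Rab6b fell 2.33-fold, 2.23-fold and 2.20-fold. The call of Dynap in all 4 lines was lost when any 1 array other than control replicate 2 was left out. That of Kif20b was lost without any 1 array other than line 63 replicate 2. The Emc8 call was kept only without either array of line 12 or without line 52 replicate 1. Independent lists would share 0.00035 higher and 0.000902 lower probe sets. Simulated unchanged cultures gave 0 in each of 100 draws, an outcome nearly fixed in advance. The 5 cultures simulated to differ by the spread measured between lines, shuffled over probe sets, gave 197 false calls. That exceeds the 29 to 66 calls of the real cultures, each set against the others, so this simulation overstated such calls on 430B. All 29 calls depended on the trended variance prior, since 0 passed without it, and 15 passed without the low-signal filter, where Dynap (adjusted p = 0.0949), Cemip (adjusted p = 0.0705) and Rab6b (adjusted p = 0.0841) were lost. Leaving out 1 array gave 8 to 21.

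Known proto-oncogenes, the group named by the series, were not shifted as a list. Of 44 tested on 430A, 4 rose in all 4 lines (Fosl1, Myc, Ets2 and Pim1), 0 fell in all 4 there, and 22 had a positive mean difference. Of 9 further members tested only on 430B, 1 fell and 0 rose in all 4 lines: Met, the hepatocyte growth factor receptor, fell 1.94-fold (13300 ± 1530 in the control, 6240 ± 1120 to 7830 ± 1410 in the lines), and was named after its values were seen. The Met call was lost without the variance trend (adjusted p = 0.418), without the low-signal filter (adjusted p = 0.0739), and when any 1 array was left out (adjusted p = 0.0521 to 0.281) except line 12 replicate 1, line 52 replicate 2 or line 63 replicate 1. The list's median was -0.000713 while its mean was 0.178, and the camera test gave adjusted p = 0.249. With genes adjusted over the list alone, lines as units, 2 members passed, against 0 over all probe sets. Myc, a transcription factor that drives growth, rose 2.34-fold (443 ± 81.8 in the control, 879 ± 54.7 to 1260 ± 13.5 in the lines) and Ets2 rose 2.29-fold. Hmga2, a chromatin architectural protein, rose 2.29-fold in all 4 lines at the probe set with the largest change, which is not the brightest one used for the list. Myc and Hmga2 were called higher by at least 2-fold in at least 3 lines. Fosl1 and Pim1 met the 2-fold limit of the naming rule only on signals under the chip's median: with these raised to the median, Fosl1 reached 2-fold in 2 lines (at least 2.15-fold in line 63 and 2.54-fold in line 72) and Pim1 in 0. No proto-oncogene on 430A was called at least 2-fold lower in at least 3 lines. The Fosl1 call in all 4 lines was lost without the low-signal filter (adjusted p = 0.0635) and without the variance trend (adjusted p = 0.0982).

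Among 29 tumour suppressors, Cdkn1a, an inhibitor of cyclin-dependent kinases and a p53 target, rose 2.96-fold in the 4 lines, from 3980 ± 193 to between 8870 ± 715 and 19100 ± 1080. Pdcd4, an inhibitor of translation initiation, and Ptch1, the hedgehog receptor, fell 1.73-fold and 1.75-fold. The list as a whole did not pass (median 0.0774, adjusted p = 0.763; 0 adjusted over the list alone). Of 25 p53 target genes, 20 had positive mean differences and 4 rose in all 4 lines: Cdkn1a, Gadd45a (2.86-fold), Ddit4 (2.08-fold) and Aen (2.08-fold). The list passed with the preset correlation (median log2 difference 0.253, adjusted p = 0.000191) but not otherwise (adjusted p = 0.366 with an estimated correlation; 0 adjusted over the list alone). Against the control with arrays as units, it passed in lines 52, 63 and 72 (adjusted p = 1.29e-06, 0.00081 and 0.00301) but not in line 12 (adjusted p = 0.116; 7 genes higher, 4 lower).

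Genes of cell division stood higher in the lines. Of 37 tested mitosis genes, 36 had positive mean differences and 5 rose in all 4 lines, among them Anln (2.56-fold), which acts in cytokinesis, Top2a (2.18-fold), a DNA topoisomerase, and the proliferation marker Mki67 (2.16-fold). The list's median log2 difference was 0.844 (camera, adjusted p = 1.06e-18 with the preset correlation and adjusted p = 0.366 with an estimated correlation; 0 adjusted over the list alone). Of 29 DNA replication genes, 27 had positive mean differences and 6 rose in all 4 lines, among them Rrm2 (3.48-fold), a ribonucleotide reductase subunit, the licensing factor Cdt1 (2.54-fold) and the helicase subunit Mcm3 (2.32-fold). The list's median was 0.428, with adjusted p = 1.7e-10 at the preset correlation and adjusted p = 0.366 with an estimated correlation, and 0 members passed adjusted over the list alone. The median of the mitosis list differed between lines, at 0.268 in line 12, 0.826 in line 52, 1.1 in line 63 and 1.25 in line 72.

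Cholesterol synthesis genes also stood higher. The list's median over the mean of the lines exceeded that of the mitosis list because of line 12 (1.46 against 0.268), while the mitosis median was the larger in lines 52, 63 and 72. All 18 tested genes had positive mean differences and 6 rose in all 4 lines. Sqle, squalene epoxidase, rose 3.27-fold, Idi1, isopentenyl diphosphate isomerase, 2.96-fold, and Fdft1, squalene synthase, 2.84-fold. On 430B Insig1, which restrains the pathway and was named after its values were seen, rose 2.62-fold in all 4 lines, a call lost without the variance trend (adjusted p = 0.228). The median log2 difference was 0.956 (adjusted p = 5.08e-12 with the preset correlation and adjusted p = 0.366 with an estimated correlation), and 4 genes passed adjusted over the list alone. In the unfolded protein and amino acid stress list, 19 of 28 genes had positive mean differences and 5 rose in all 4 lines, among them Chac1 (2.66-fold), Trib3 (2.34-fold) and Herpud1 (2.09-fold). Its median was 0.2, with adjusted p = 0.00323 at the preset correlation and adjusted p = 0.366 with an estimated correlation, and 2 genes passed adjusted over the list alone.

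Matrix, contractile and Wnt genes stood lower over the mean of the lines, but not in each line by the list test. Of 36 collagen and fibrillar matrix genes, 5 fell in all 4 lines (Postn, Thbs1, Col6a3, Col6a1 and Col5a1) and 2 rose (Fbln1 and Ecm1). Thbs1, a matricellular glycoprotein, fell 2.03-fold and Col6a3 1.91-fold, while Fbln1, another matrix glycoprotein, was at least 2.72-fold higher. The median was -0.362 (adjusted p = 0.000546 with the preset correlation and adjusted p = 0.366 with an estimated correlation; 0 adjusted over the list alone). Of 26 contractile and actin genes, Myl9 (2.88-fold), Zyx (1.71-fold, with another probe set of opposite sign), Vcl (1.61-fold) and Cnn2 (1.55-fold) fell in all 4 lines. That list had a median of -0.204, with adjusted p = 0.0183 at the preset correlation and adjusted p = 0.366 with an estimated correlation, and 0 genes passed adjusted over the list alone. Of 12 Wnt and Notch genes, Wnt5a and Tcf7l2 (1.86-fold) fell in all 4 lines (median -0.389, adjusted p = 0.0242 with the preset correlation and adjusted p = 0.366 with an estimated correlation; 0 adjusted over the list alone). Against the control with arrays as units, the collagen list did not pass in line 12 (adjusted p = 0.155; 9 genes higher, 14 lower), the contractile list not in lines 12 and 52 (0.109 and 0.202), and the Wnt and Notch list only in line 72 (4.19e-05, against 0.109, 0.0645 and 0.137 in lines 12, 52 and 63). The unfolded protein list did not pass in line 52 (0.303), and the mitosis, DNA replication and cholesterol lists passed in all 4 lines. These 8 lists were called of 26 tested, and 0 were called with an estimated correlation. The size of the correlation alone does not account for that loss. The estimate was 0.782 for the mitosis list, but -0.00496 for the contractile list and -0.0311 for the Wnt and Notch list, under the preset 0.01. The unadjusted camera p of these 2 lists still rose, from 0.00492 to 0.0515 and from 0.00743 to 0.0667. With each line in the control's place, 4 lists were called for line 12, 4 for line 52, 7 for line 63 and 7 for line 72.

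**Figure D3:**
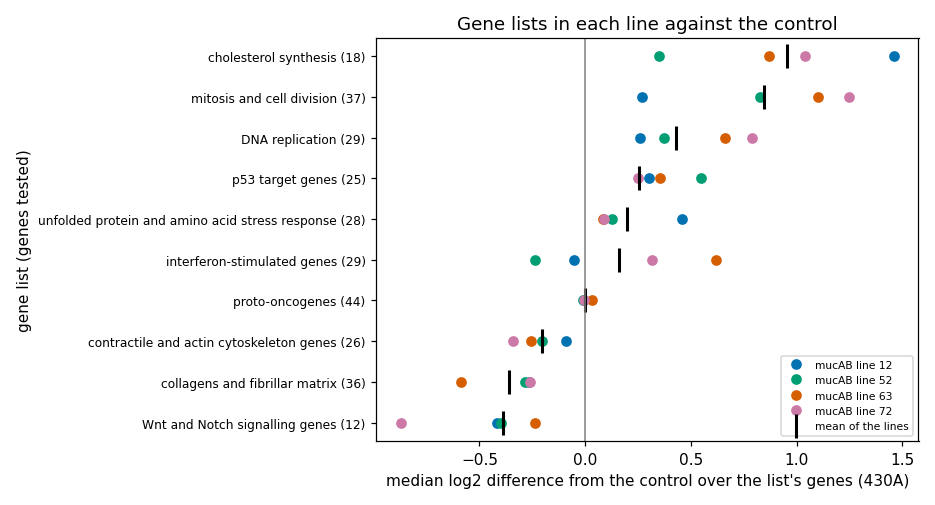
Median log2 difference from the control (x axis) over the genes of the 8 called lists, the proto-oncogenes and the interferon-stimulated genes (y axis, genes tested in brackets) in each line (points) and over the mean of the lines (black bars), on 430A. Cholesterol synthesis ranges from 0.35 in line 52 to 1.46 in line 12, and the proto-oncogene medians lie close to 0 in every line.

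The remaining lists did not pass. The list of DNA polymerase and translesion synthesis genes mixes host relatives of the mucAB polymerase with replicative and repair polymerases and accessory factors. Its 25 tested genes had a median of 0.0686 (adjusted p = 0.215), with Pcna, the polymerase clamp, up 1.57-fold and Pole4 down 1.61-fold in all 4 lines. The 44 DNA damage response and repair genes had a median of 0.00229 (adjusted p = 0.439), and Apex1, an abasic site endonuclease, rose 1.77-fold. The promoter of the introduced gene is that of a metallothionein gene, and 0 of 9 metallothionein and metal response genes were called in all 4 lines (adjusted p = 0.311). Mt2 read 183 ± 85.2 to 250 ± 27.8 in the lines and 113 ± 56.8 in the control. Among members with the smallest p that were not called in all 4 lines, the mean of the lines lay at least 1.59-fold above the control for the mitotic kinesin Kif2c, at least 1.34-fold for the checkpoint kinase Chek1 and 1.92-fold for the polymerase subunit Pole2. Members called in all 4 lines also occurred in the growth factor and MAPK list (3 higher, 1 lower, Spry2 2.45-fold; adjusted p = 0.567; 4 adjusted over the list alone), the inflammatory list (Ccl8 2.61-fold higher, Vcam1 2.60-fold and Cx3cl1 2.34-fold lower; adjusted p = 0.763; 1 adjusted over the list alone) and the NRF2 list (Taldo1 2.11-fold and Sqstm1 1.55-fold higher; adjusted p = 0.109).

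The glycolysis list had 2 genes higher in all 4 lines, Pkm 1.75-fold and Pgk1 1.49-fold (adjusted p = 0.109). The protease list held Ctsd 1.53-fold higher and Reck 2.33-fold and Mmp9 2.08-fold lower (median 0.0835, mean -0.0602, adjusted p = 0.763), and the TGF-beta and BMP list Tgfbi 1.61-fold higher and Smad6 2.05-fold and Bmpr1a 1.77-fold lower (adjusted p = 0.596). Of 21 secreted growth factors only Hbegf, at least 1.34-fold higher, was called in all 4 lines (adjusted p = 0.538). No member was called in all 4 lines among 29 interferon-stimulated genes (adjusted p = 0.111), 13 MHC class I genes (0.301), 29 mesenchymal and adhesion genes (0.115), 30 ribosomal protein genes (0.1), 27 apoptosis regulators (0.439) or 13 fibroblast markers (0.219). Vim, the fibroblast intermediate filament, read 93900 ± 20100 in the control and 69800 ± 10900 to 81300 ± 4240 in the lines. Markers of other cell types had few tested genes: 4 for adipocytes, 2 for bone and cartilage, 2 for muscle, 4 for macrophages and leukocytes, and 0 for epithelium, endothelium and the Y chromosome. None of these was called in all 4 lines. Members with the smallest p among those not called in all 4 lines had mean log2 differences of 1.18 (Rsad2) and 0.41 (Ifi35) for interferon, 0.47 (B2m) and -0.48 (Tap2) for MHC class I, 0.60 (Vegfa) for secreted growth factors, -0.86 (Ncam1) for adhesion, -0.52 (Rpl22) and -0.25 (Rps9) for ribosomes, 1.06 (Birc5) and -0.58 (Casp6) for apoptosis, and -0.55 (Pdgfra) for fibroblasts. In the lists that did not pass, other than the proto-oncogene, growth factor and MAPK, and inflammatory lists, 0 genes passed adjusted over the list alone. Without the variance trend, calls in all 4 lines were lost for Apex1 (adjusted p = 0.0963), Bmpr1a (0.114), Tgfbi (0.0667), Ctsd (0.0726) and Sqstm1 (0.052). In the called lists they were lost for Aen (0.0731), Cks2 (0.0826), Cnn2 (0.0703), Herpud1 (0.0647), Chac1 (0.0579), Slc7a5 (0.0913) and Tcf7l2 (0.0833). Without the low-signal filter they were lost for Apex1 (0.0544), Bmpr1a (0.0693), Aen (0.055), Tcf7l2 (0.0738), Mcm5 (0.0932) and Slc7a5 (0.0513). After quantile normalization the call was lost for Tcf7l2 (0.0539), and with the offset of 32 for Mcm5 (0.0529). With the replicate number as a block, calls were lost for Bmpr1a (0.0515), Tcf7l2 (0.0577) and Mcm5 (0.0601).

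Taken line by line, each mucAB line differed from the control at 15.1 to 23.1 percent of the tested 430A probe sets. Line 12 had 2732 calls (1236 higher, 1496 lower), line 52 had 2830 (1312 and 1518), line 63 had 2582 (1250 and 1332) and line 72 had 1850 (916 and 934). On 430B the counts were 469, 505, 440 and 273. Of the 5588 probe sets called in at least 1 line on 430A, 2820 were called in exactly 1 line and 340 were called higher in 1 line and lower in another. Without the variance trend the 430B counts were 5, 5, 3 and 3. Leaving out 1 array moved these counts by more than 1.5 times in several cases, down to 836 for line 72 on 430A without its replicate 1.

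Each line also had genes that met a limit of 4-fold, on the signals as deposited, both from the control and from the mean of the other 3 lines. Many of these rest on signals under the chip's median, for which only the bounds below hold. In line 52, Abi3bp, an extracellular matrix protein, was 17.4-fold higher than in the control (5760 against 330) and Igf2, an insulin-like growth factor, 12.9-fold higher (8280 against 644), while Rhox5, a homeobox gene, was at least 28.9-fold lower (157 against 6960). Heph was at least 4.39-fold higher there, Atp1b1 at least 1.71-fold and Tinag at least 1.06-fold lower. In line 12, Slc40a1, the iron exporter ferroportin, rose 8.10-fold and Isoc1 5-fold, Mfhas1 was at least 2.15-fold higher, and Ank3 at least 2.21-fold and Agt, angiotensinogen, at least 1.53-fold lower. In line 63, Anxa8 was at least 14.0-fold, AU021092 at least 6.66-fold and Afp, alpha-fetoprotein, at least 2.05-fold higher, and Nsg1 at least 1.57-fold lower. In line 72, Rims2 was at least 1.60-fold higher. Sorcs2 in line 12, Mfhas1 and Tcea3 in line 63, and Naaa and Angpt1 in line 72 were lower with both sides under the chip's median, and Il17ra in line 72 allowed no bound above 1. Each of these differed from the control and from the mean of the other 3 lines with an adjusted p between 2.19e-08 and 0.0301. The Rims2 call was lost without the variance trend (adjusted p = 0.053) and without the low-signal filter (adjusted p = 0.0528), and without line 72 replicate 1 or 2 or control replicate 2 (adjusted p = 0.203, 0.153 and 0.177). The Mfhas1 call in line 12 was lost without either of its arrays or control replicate 1 (adjusted p = 0.0564, 0.0522 and 0.102). Other lines could share such a difference: Mfhas1 read 603 ± 40.6 in line 52 beside 517 ± 12.9 in line 12, and Slc40a1 and Anxa8 were called higher in all 4 lines. Counts of such genes on the signals as deposited, higher and lower, were 3 and 15 in line 12, 19 and 14 in line 52, 4 and 20 in line 63, and 1 and 10 in line 72.

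The 4 lines also differed from each other. The F test among lines called 5137 probe sets on 430A (41.8 percent) and 1131 on 430B (7.85 percent; 31 without the variance trend). Pairs of lines differed at 1580 probe sets (lines 63 and 72) to 3316 (lines 52 and 72) on 430A, beside 1850 to 2830 for a line and the control. The median SD between the 4 line means was 0.254 on 430A. Interferon-stimulated genes were among those that differed: 25 of 29 were called by the F test. Ifit3, an interferon-induced antiviral protein, read 4488.7 in line 12, 5332.5 in line 52, 13975.8 in line 63, 11798.7 in line 72 and 4860.5 in the control, and the chemokine Cxcl10 read 440.8, 478.5, 1600.4, 770.5 and 383.9. Psmb8, an immunoproteasome subunit, went against the list in line 63, at 182.6 beside 877.2 in the control (log2 difference -2.26, adjusted p = 2.96e-06). Ifit3, Cxcl10 and Psmb8 were chosen after their values were seen. Against the other 3 lines, the interferon list was higher in line 63 (median 0.686, adjusted p = 9.44e-11) and line 72 (0.238, adjusted p = 2.07e-05) and lower in line 12 (-0.334, adjusted p = 1.94e-06) and line 52 (-0.551, adjusted p = 3.66e-08). With a correlation estimated from the residuals between the 2 arrays of a culture, these adjusted p-values were 0.0138, 0.0298, 0.0186 and 0.025. The 4 contrasts are linked, since each sets a line against the others. Against the control, camera with the preset correlation called the list higher in line 63 (median 0.621, adjusted p = 1.07e-08) and line 72 (0.317, adjusted p = 3.22e-06). It was not called in line 12 (-0.0508, adjusted p = 0.397) or line 52 (-0.238, adjusted p = 0.0645). These tests among lines ran over arrays, so they measure a spread that may be technical. The mitosis list was lower in line 12 (-0.701, adjusted p = 6.11e-13) and higher in line 72 (0.532, adjusted p = 1.41e-08), with adjusted p = 0.0154 and 0.0298 with an estimated correlation. Cholesterol synthesis was higher in line 12 (0.421, adjusted p = 1.08e-06) and lower in line 52 (-0.568, adjusted p = 5.19e-07), with adjusted p = 0.0186 and 0.025 with an estimated correlation.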

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

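The tests of scaling, those that put each culture alone for the shared calls and the mitosis list, and the test for leukocytes were chosen after the results they bear on had been seen; the same splits for the lines against the control were planned, with the prediction written afterwards.

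The first pattern is the set of 368 probe sets on 430A, and 29 on 430B, called the same way in all 4 lines. A single scaling factor for the control, or for each line, moves all probe sets of an array the same way. The shared calls ran both ways, 194 higher and 174 lower on 430A and 17 and 12 on 430B. On 430A, 86 higher and 58 lower were at least 2-fold in the mean. This argues against such factors as the source of both directions, but not of 1 of them. The common level of the arrays itself favours calls both ways, so the balance is no further test. Searches over factors decide nothing further. The factor for the control that left the fewest calls left 362 on 430A and 28 on 430B. Those minima lay at shifts of -0.02 and -0.08, near where the common scaling had already put the arrays. Separate factors per line ended at 39 and 5 by shifting lines in opposite directions, which ends agreement whatever its source. Quantile normalization gives all arrays the same distribution of signals, which removes a difference between arrays that depends on signal level alone. It moved line-minus-control differences by little (5th to 95th percentile -0.0229 to 0.0648 on 430A). After it, 375 probe sets on 430A were called the same way in all 4 lines. These values argue against such a difference as the source of the 368. On 430B the differences moved by -0.0739 to 0.0266, also little. Of the 5 splits of the cultures into 1 and 4, 2 gave as many shared calls on 430A (highest other 566) and all 5 did on 430B (highest other 66), and with cultures as units 5 of 5 splits gave as many as the real 0 on 430A (highest other 0) and 3 of 5 as many as the real 3 on 430B (highest other 9). Since 5 splits cannot give a share under 0.05, an effect of mucAB, of transformation, of selection or cloning, and an ordinary difference of 1 culture from others stay open and cannot be told apart.

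The second pattern is the higher level of mitosis genes in the lines. Scaling by 1 factor per array moves the list and the other genes alike, so it cannot open a gap between them. The list's median was 0.844, with 36 of 37 genes positive, against -0.0253 over all tested probe sets. That the gap does not come from such scaling follows from this arithmetic, and the values are no test of it. The common level of the arrays holds the median over all tested probe sets near 0. The list passed camera with the preset correlation but not with an estimated one (adjusted p = 0.366). Whether the gap exceeds the spread between cultures therefore stays undecided. A control culture closer to growth arrest may account for it, but a list of 22 genes of arrested fibroblasts, written before this test, had a median of -0.0562 with 10 of 19 tested genes lower, which decides nothing. With each culture alone, 1 of 5 splits gave a list median as far from 0, the real one (0.844; the next was -0.696 for line 72), and 5 splits are too few for a share under 0.05. A difference between arrays that depends on signal level alone would be removed by quantile normalization. That step moved line-minus-control differences on 430A by -0.0229 to 0.0648 (5th to 95th percentile). Beside the list's median of 0.844, these values argue against such a difference as the source. An effect of mucAB stays open and untested, as do transformation and growth rate at harvest.

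The third pattern is the interferon list, higher in line 63 and in line 72, each against the other 3 lines. Scaling by 1 factor per array, which moves the list and the other genes alike, is argued against, since the list differed from the other genes with the preset and the estimated correlation (adjusted p = 0.0138 in line 63 and 0.0298 in line 72 with the estimated one). Leukocytes mixed into these cultures might bring such genes: of 7 abundant leukocyte transcripts, 1 reached the chip's median in line 63 or 72. That was Lyz2, with 255.3 in line 72 and 185.2 in line 63 against 368.7 in line 12 and 317.5 in the control, and the others stayed under the median, up to 196.3 for Laptm5 in line 63. Mpeg1, at 115 and 157.3 in lines 63 and 72 against 12 to 27 elsewhere, went with the explanation, so the source stays open. A difference between arrays that depends on signal level also stays open. The shift by quantile normalization was taken for the lines minus the control, not for a line against the other 3. No biological explanation was tested, because the labels give no difference between the lines.

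Among named genes, 1 line lay far from the other 3, by the gap over the range, for Msln (0.842), Pim1 (0.861), Lgals7 (0.95), Dusp4 (0.891), Col6a1 (0.904), Mmp9 (0.942) and Insig1 (0.841). The same held for the medians of the proto-oncogene list (0.883), the collagen list (0.924) and the unfolded protein list (0.887). The measure is relative to the range, and the proto-oncogene medians all lay between -0.0114 in line 52 and 0.0323 in line 63. Chance marks about 1 in 20 groups in this way.

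The difference from the control itself differed between lines, by the F test in limma, for these genes of the largest shared changes: Itgbl1 (adjusted p = 0.000126), Anxa8 (0.000279), Tnfrsf21 (0.0172), Pim1 (0.0372), Wnt5a (0.000274), Postn (5.12e-06), Pcdhb9 (1.2e-06), Lgals7 (0.0249), Ptx3 (0.000223), Peg3 (1.32e-05), Pcdh18 (0.0133), Dynap (0.00014), Cemip (5.7e-07) and Sned1 (4.09e-05). Among members of the gene lists it differed for Ets2 (6.14e-05), Hmga2 (0.036), Cdkn1a (2.37e-05), Ptch1 (0.0204), Gadd45a (0.000163), Aen (0.00412), Pcna (0.0345), Pole4 (0.0136), Apex1 (0.000289), Rrm2 (0.000166), Cdt1 (0.00623), Mcm7 (0.000337), Mcm3 (0.00369), Mcm5 (0.00292), Mki67 (0.00704), Cks2 (0.00105), Top2a (0.000325), Anln (5.64e-05), Kif20a (0.0355), Col6a3 (0.000468), Thbs1 (0.000313), Ecm1 (0.0262), Fbln1 (4.05e-05), Cnn2 (0.0104), Vcl (0.0034), Myl9 (4.72e-06), Reck (0.0199), Ctsd (0.0458), Mmp9 (9.95e-06), Taldo1 (0.00125), Sqstm1 (0.00277), Rsad2 (2.38e-06), Ifi35 (0.00349), Tap2 (0.000505), Vcam1 (0.000246), Cx3cl1 (0.00955), Ccl8 (4.12e-05), Ncam1 (8.87e-05), Pkm (0.0307), Sqle (0.0106), Idi1 (0.000281), Ebp (0.000142), Msmo1 (1.37e-07), Fdft1 (2.39e-05), Insig1 (0.000335), Atf4 (0.0134), Slc7a5 (0.0479), Trib3 (0.000532), Birc5 (0.001), Smad6 (0.0177), Bmpr1a (0.00125), Tgfbi (0.000807), Tcf7l2 (0.000959), Pdgfra (0.00142), Scd1 (0.00105), Lpl (1.9e-05), Omd (1.62e-06) and Cd14 (0.0449). Among the genes that set single lines apart, chosen for such a difference, it differed for Mfhas1 (1.36e-05), Isoc1 (2.01e-07), Slc40a1 (2.01e-07), Agt (5.89e-07), Sorcs2 (0.000345), Ank3 (1.18e-05), Abi3bp (1.72e-07), Igf2 (2.99e-08), Heph (0.00133), Atp1b1 (4.25e-06), Tinag (0.000135), Rhox5 (1.51e-08), AU021092 (0.000146), Afp (0.00195), Nsg1 (4.42e-05), Tcea3 (0.000164), Naaa (0.000246), Angpt1 (0.000284) and Il17ra (5.81e-05). Lists that differed between a line and the other 3 with the preset and the estimated correlation, over arrays and so against a spread that may be technical, had these median log2 differences. In line 12 they were -0.378 for DNA replication, -0.701 for mitosis, -0.334 for interferon and 0.421 for cholesterol synthesis genes. In line 52 they were -0.551 for interferon and -0.568 for cholesterol synthesis genes, and in line 63 0.686 for interferon and 0.513 for inflammatory genes. In line 72 they were 0.414 for DNA replication, 0.532 for mitosis, 0.238 for interferon and 0.516 for MHC class I genes.

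Control probe sets outside the comparisons gave signals above both control arrays. For the B1 repeat, the ratio of the line's mean to the control's was 2.63 in line 12, 2.26 in line 52 and 2.03 in line 72 on 430A, and 2.96, 2.51 and 2.27 on 430B. For the B2 repeat it was 1.31, 1.21 and 1.40 in lines 12, 52 and 63 on 430A, and 1.40, 1.24, 1.41 and 1.26 in lines 12, 52, 63 and 72 on 430B. For 18S ribosomal RNA it was 1.30, 1.82 and 1.48 in lines 12, 52 and 72 on 430A and 1.42, 2.14 and 1.77 on 430B. Line 63 went the other way on 430A, with 18S signals of 27900 and 28200 under both control arrays (34900 and 29500). The other lines not given for a probe set overlapped the control arrays.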

How the results depend on the processing

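Leaving out each line for the counts over 4 lines and for the lists was chosen after seeing the data; the other alternatives were planned. Of 804 values of named genes under settings other than leaving out an array, 0 reversed, 50 were no longer called and 3 became called; with 1 array left out, 0 of 1410 reversed, 224 were no longer called and 6 became called. The counts for 430A, except that of the lines against the control, stayed within 1.5 times under quantile normalization, both filters, the offset, the untrended prior and the replicate block. With arrays as units, the lines against the control had 2570 calls on 430A and 395 on 430B, against 0 and 3 with lines as units; that fit takes only the spread between the arrays of a culture as error. The lists fell from 8 to 0 with an estimated correlation, and gave 6 to 11 without 1 line.

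On 430B the untrended prior gave 0 for the lines against the control, 5, 5, 3 and 3 for lines 12, 52, 63 and 72, 31 for the differences among lines and 0 for the calls in all 4 lines; the cause was not tested. No filter and the stricter filter each gave 0 for the lines against the control, and no filter gave 15 in all 4 lines, where more probe sets were tested. Signals under the median of a design give only bounds on folds. On 430B the median SD between arrays of a culture was 0.571 and that between line means, each of 2 arrays, 0.476.

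With 1 array left out, a lone array is assumed to vary like the other groups. On 430A the ranges were 0 to 4 for the lines against the control, 1757 to 2630 for line 12, 1674 to 3201 for line 52, 1456 to 2932 for line 63, 836 to 2121 for line 72, 4100 to 5290 among lines, 190 to 400 in all 4 lines, and 8 to 9 lists. On 430B they were 0 to 10, 203 to 467, 195 to 501, 198 to 430, 127 to 263, 742 to 1022 and 8 to 21. The counts fell most without an array of the line concerned or of the control: line 52 on 430A to 1817 and 1712 without its replicates 1 and 2, line 63 to 1487 and 1456, line 72 to 836 and 948, and without control replicate 1 lines 12, 52, 63 and 72 to 1757, 1674, 1575 and 946, with 1178 for line 72 without control replicate 2. On 430B each line's count moved by over 1.5 times without either of its own arrays or either control array, and the calls in all 4 lines did so without any array but line 63 replicate 1. Without line 52 or 72, the calls shared by the other 3 lines were 607 and 621 on 430A (481 to 621 over the 4 lines), and 42 to 71 on 430B, with 46, 55 and 71 without lines 12, 52 and 72; requiring 3 lines asks less than requiring 4. The lines against the control then had 0 to 1 calls on 430A and 0 to 2 on 430B.

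Deviations of same-numbered arrays correlated weakly, at -0.107 to 0.0863 on 430A and -0.0273 to 0.0436 on 430B. These values do not exclude a shift that follows the replicate number. On 430B the Gapdh signal ratio was higher in the higher-numbered array of every culture. The replicate block raised every count given below on 430B and lowered every count on 430A. With the replicate number as a block, lines 12, 52, 63 and 72 had 2716, 2771, 2538 and 1773 calls on 430A and 546, 582, 483 and 329 on 430B, the F test 5038 and 1277, and the calls in all 4 lines were 360 and 31. The lines against the control with arrays as units and the replicate block had 2553 and 458.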
